A study of Homo sapiens with 6 samples.

How the data were processed

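RNA was sequenced from a conditionally immortalised human podocyte cell line (M. Saleem), a culture model of the epithelial cells that cover the glomerular capillaries of the kidney. The 6 libraries fall into 3 groups of 2. They are control cells, cells given 1 mM dimethyloxalylglycine (DMOG) for 16 h, and cells held in hypoxia for 16 h. The treatment label of the first group reads only control, so whether these cells received a vehicle is not known here. DMOG is a cell-permeable 2-oxoglutarate analog that blocks the prolyl hydroxylases which mark hypoxia-inducible factor (HIF) for degradation, together with other 2-oxoglutarate-dependent enzymes. Per the labels' protocols, proliferating cells were kept at 33 °C and cells were differentiated at 37 °C for 10 days. The labels do not say whether the treated cultures were differentiated, and they give no oxygen level for the hypoxia group. Per the series' design text the duplicates are biological, and no library batch or day is given.

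The deposited values are length- and depth-scaled expression values per gene (TPM), made by the authors. Per the submitters' processing notes, cutadapt 1.18 and STAR 2.6.1c were used with genome build GRCh38. The gene annotation, the counting tool and the use of strand in counting are not given in the sources used here. Each column sums to 1000000, so the values carry no depth and a rise of abundant transcripts lowers all others. The table holds 60609 Ensembl gene IDs, of which 60295 were matched to a symbol and 58457 to a position in GENCODE release 29 on GRCh38. All coordinates given are 1-based and from that annotation. In all 6 libraries, 29040 gene IDs are listed at 0. No pair of libraries holds identical values, and 0 columns of values were left unused.

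Low TPM values step in whole multiples of the value of 1 read. Between control replicate 1 and each other library, from 93.6% to 95.6% of ratios among low genes (under 0.5 TPM) lay within 0.0005 of a whole-number ratio, after scaling by the step. With exonic lengths from GENCODE release 29, the steps gave an estimated 15989769 to 19643673 reads in genes per library. Of the values below 100 estimated reads, 72.7% to 75.1% came out whole within 0.02 reads, so these lengths are not those the authors used for every gene and the reads are estimates. Of 16820 tested genes with a length, 2123 had fewer than 10 estimated reads per library on average. The median length of those genes was 440 bases.

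Genes with a mean of at least 1 TPM over the 6 libraries were tested, which left 16969. Values were transformed to log2(TPM + 1), and limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend) was fitted to all 6 libraries with a mean per group. The groups thus shared their estimate of the spread, with 3 residual degrees of freedom and 3.23 prior degrees of freedom. Tests were 2-sided, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. Adjusted p-values of genes below come from this limma test. A fold change is on the log2(TPM + 1) scale, which understates the change of low genes, and ± after a log2 fold change is its standard error (SE). Group values are mean TPM ± SD of 2 libraries. The 3 comparisons were DMOG versus control, hypoxia versus control, and DMOG versus hypoxia, the last of which tests the difference between the stimuli.

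Before the data were examined, 28 lists with 578 different genes were fixed for HIF targets, metabolism, matrix, podocyte and other kidney cell types, stress, inflammation and growth. Lists share genes, so their results are not independent. Some HIF targets are also in the oxygen sensing, glycolysis, demethylase, collagen, angiogenic, stress response and chaperone lists. Lists with at least 4 tested members were tested with camera (limma) at a preset correlation of 0.01, adjusted over the lists of a comparison. This left out the endothelial and leukocyte markers. No list in any of the 3 comparisons passed the threshold when camera estimated the correlation within each list, and that adjusted p is given beside each call. That version rests on 3 residual degrees of freedom, and its power was not simulated. The HIF targets with DMOG, with 32 of 32 fold changes above 0, had adjusted p = 0.103 in it. Members were counted as past the threshold over all genes tested and, separately, adjusted over the list alone.

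The genes named were chosen by a rule fixed before the data were examined. It takes the 10 largest rises and 10 largest falls against control (8 and 8 between the stimuli) among genes past the threshold with a symbol, both libraries of a group above both of the other, and a mean of at least 5 TPM in the higher group. Where no gene passed in a direction, it takes the 5 with the smallest unadjusted p. It also takes all tested members of the HIF target and oxygen sensing lists. From each other list it takes up to 2 members each way with the smallest adjusted p, or the 2 with the highest mean TPM where no member passed. Because the rule took many short RNAs with few reads, the same ranking among genes with at least 10 estimated reads is also given. That ranking was chosen after the values were seen. Of 203 genes taken by either ranking or by the lists, 87 overlap another annotated gene with a mean of at least 1 TPM, so reads at those loci can be ambiguous.

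The fit was tested on simulated data for DMOG versus control over 16969 genes. In 10 repeats, 200 genes were changed with noise drawn from the fitted spread. The test called 12.4% of genes changed by 0.5, 54.8% of genes changed by 1 and 77.7% of genes changed by 2 on the log2 scale. It called 6.3 unchanged genes per repeat. With the HIF targets shifted by 0.5, camera called that list in 10 of 10 repeats, and called 1.3 other lists per repeat. Some of the other lists hold shifted HIF targets, so this is not a rate of false calls. Simulated noise was independent between genes, and only the preset correlation was used. The simulation therefore cannot show how camera behaves where the genes of a list vary together.

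Both stimuli were compared with the same 2 control libraries, so overlap between the comparisons was set beside 100 simulations of unchanged groups against shared controls. Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 TPM, median-ratio and quantile scaling, removal of mitochondrially encoded genes, fits of 2 groups, no trend, a robust prior, an absolute log2 fold change of at least 1, an estimated camera correlation, and leaving out each library. A filter of at least 10 estimated reads and limma's voom on the estimated reads were added after seeing the data. Python 3.11.15 and matplotlib 3.10.9 were used for reading and plotting.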

Results

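Gene expression was measured by RNA sequencing in a human podocyte cell line. Chemical inhibition of the oxygen-sensing hydroxylases with DMOG and low oxygen, 2 ways of engaging the HIF pathway, were each compared with control cells. Each of the 3 groups held 2 biological replicates. Estimated reads in genes were 17512829 and 15989769 in control replicates 1 and 2, 16503502 and 17917957 with DMOG, and 17461968 and 19643673 in hypoxia. From 22417 to 24941 genes had a value above 0 TPM per library.

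On the log2(TPM + 1) scale, the control replicates correlated across genes with r = 0.971, the DMOG replicates with r = 0.963 and the hypoxia replicates with r = 0.961. Each DMOG library correlated with the control libraries at r = 0.943 to 0.950, below every replicate pair. Hypoxia and control libraries correlated at r = 0.961 to 0.963, about the value of the hypoxia pair itself. Genes are not independent replicates, and these values describe the libraries only. Mitochondrially encoded transcripts took 4.70% and 5.32% of the TPM in the control libraries, 7.92% and 7.25% with DMOG, and 5.70% and 9.10% in hypoxia replicates 1 and 2. Hypoxia replicate 2 thus stood apart from its partner in this measure. Transcripts of ribosomal proteins took 6.53% and 6.79% in control, 5.75% and 5.86% with DMOG, and 6.05% and 5.39% in hypoxia.

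The first comparison asks which transcripts change when the hydroxylases are inhibited by DMOG. HIF target genes rose almost as a block: 30 of the 32 tested canonical targets were higher with DMOG, none was lower, and the median log2 fold change was 1.42. NDRG1, a hypoxia-induced gene (ENSG00000104419, chromosome 8, 133237171 to 133302022, minus strand), rose from 28.8 ± 1.64 to 938.7 ± 4.73 TPM, a log2 fold change of 4.98 ± 0.10 (adjusted p = 4.43e-05). Carbonic anhydrase 9 (CA9), a standard HIF marker that is nearly silent in normoxic cells, rose from 0.888 ± 0.157 to 27.6 ± 3.89 TPM (log2 fold change 3.91 ± 0.31, adjusted p = 0.00181). The angiogenic growth factor VEGFA rose from 67.3 ± 0.0539 to 352.6 ± 17.8 TPM (2.37 ± 0.16 on the log2 scale), and ANGPTL4, a secreted lipase inhibitor, rose from 170.3 ± 15 to 1487 ± 261 TPM (3.11 ± 0.14). The mitophagy receptors BNIP3 and BNIP3L rose by 1.5 ± 0.10 and 1.49 ± 0.10. ANKRD37 (0.77 ± 0.29, adjusted p = 0.108) and NDUFA4L2 (0.27 ± 0.28, adjusted p = 0.528) did not pass the threshold. Camera placed the list above other genes (adjusted p = 6.44e-30, and adjusted p = 0.103 with an estimated correlation), and 31 members were higher when adjusted over the list alone.

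Of 14 tested genes for HIF subunits and their regulators, 5 were higher and 1 was lower. The HIF prolyl hydroxylase genes EGLN3 and EGLN1 rose by 2.23 ± 0.30 and 1.00 ± 0.12, and EPAS1, which encodes HIF-2α, rose from 166.2 ± 1.63 to 235.6 ± 22.7 TPM (0.50 ± 0.11, adjusted p = 0.0287). HIF1A, which encodes HIF-1α (ENSG00000100644, chromosome 14, 61695513 to 61748259, plus strand), was lower, at 55.5 ± 9.90 against 322.2 ± 6.21 TPM (log2 fold change −2.53 ± 0.13, adjusted p = 0.000544). HIF1A-AS3, a long non-coding RNA annotated on the opposite strand at 61715558 to 61751097, rose from 13.5 ± 2.11 to 138.6 ± 35.5 TPM (3.25 ± 0.19, adjusted p = 0.000761). The annotated genes overlap and the use of strand in counting is not given, so both values are uncertain to the extent that reads were shared. VHL (−0.25 ± 0.11, adjusted p = 0.148), HIF1AN (0.04 ± 0.10) and EGLN2 (0.50 ± 0.28) did not pass. The list as a whole did not pass (adjusted p = 0.0556), but it lay above other genes under 6 alternatives (adjusted p = 0.0314 to 0.0467), among them no filter, median-ratio scaling and a fit of the 2 groups alone.

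**Figure D1:**
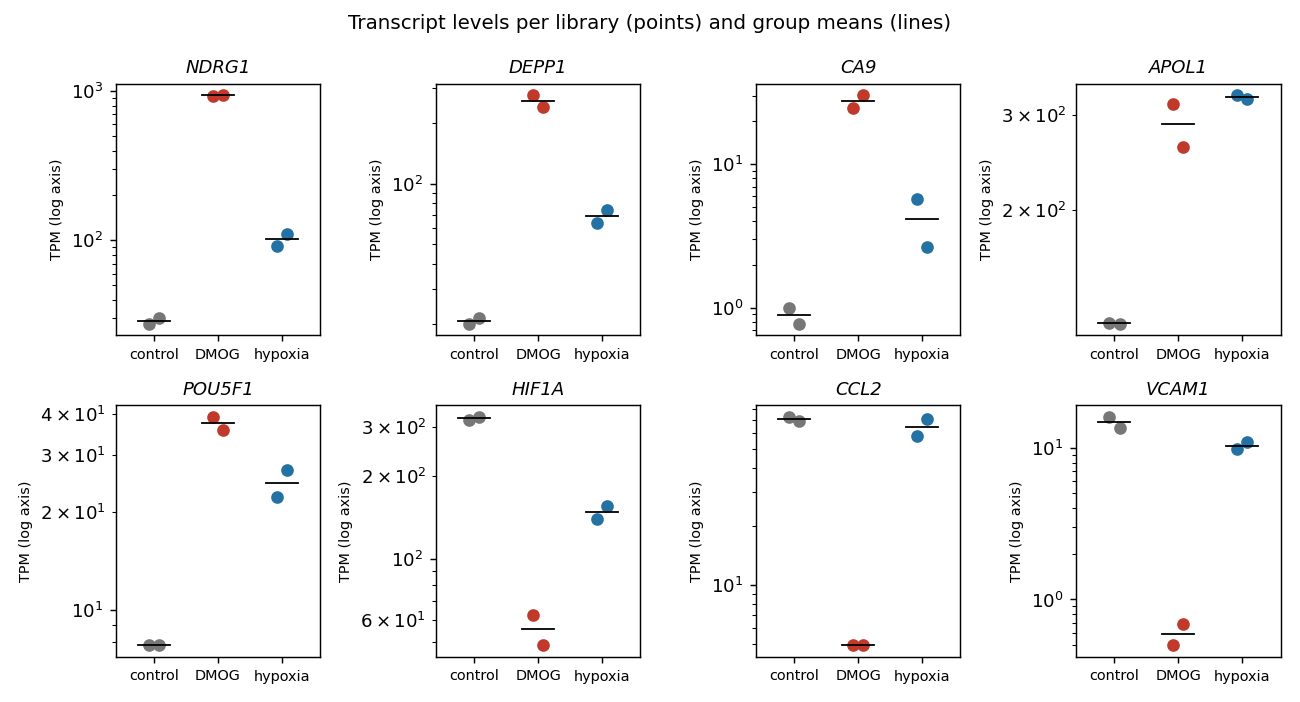
TPM on log axes for 8 genes in the control, DMOG and hypoxia groups, with a point per library and a line at the group mean. NDRG1 has means of 28.8, 938.7 and 101.6 TPM in control, DMOG and hypoxia, and HIF1A has 322.2, 55.5 and 147.1 TPM. CCL2 and VCAM1 are far lower in both DMOG libraries than in any control or hypoxia library.

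Energy metabolism genes moved in opposite directions. Of 21 glycolysis genes, 19 were higher with DMOG and only PFKM was lower (−0.51 ± 0.09), with a list median of 0.70 (camera adjusted p = 1.56e-14, and adjusted p = 0.103 with an estimated correlation). PGK1, LDHA, SLC2A1, SLC2A3, PFKFB3 and PFKFB4 in this list are also HIF targets, as are KDM3A, P4HA1 and ERO1A, named for other lists below. Hexokinase 2 (HK2) rose from 19.4 ± 0.542 to 159.6 ± 13.8 TPM (2.98 ± 0.10), and the glucose transporter gene SLC2A1 from 272.6 ± 4.05 to 996.5 ± 53.1 TPM (1.87 ± 0.07). Of 43 nuclear genes of the respiratory chain, none was higher and 22 were lower, among them ATP5PB (−0.63 ± 0.10) and NDUFB10 (−0.60 ± 0.08), with a median of −0.39 (camera adjusted p = 4.10e-08, and adjusted p = 0.281 with an estimated correlation). Of 13 mitochondrially encoded genes, MT-CO2 alone passed, with 14737 ± 179 against 6670 ± 489 TPM (1.15 ± 0.20). That list had a median of 0.54 (adjusted p = 0.0307, and adjusted p = 0.603 with an estimated correlation) and did not pass with quantile normalization (adjusted p = 0.2345) or without control replicate 1 (adjusted p = 0.105) or DMOG replicate 1 (adjusted p = 0.152). In the TCA cycle 4 of 19 genes were lower, with fumarate hydratase (FH) at −0.89 ± 0.09, and IDH2 was higher (0.33 ± 0.07). Its adjusted p of 0.0474 (0.50 with an estimated correlation) was above the threshold under 8 further alternatives, including median-ratio scaling (adjusted p = 0.115).

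In the lists of 2-oxoglutarate-dependent demethylases, of collagen hydroxylation and crosslinking, and of matrix, more members passed as higher than as lower. Among 22 genes of the chromatin and RNA demethylase list 9 were higher, among them KDM3A (1.42 ± 0.13) and ALKBH5 (0.57 ± 0.07). The 2 lower members were the ribosomal oxygenase genes RIOX1 (−0.67 ± 0.09) and RIOX2 (−0.60 ± 0.13). That list had a median of 0.34 (camera adjusted p = 0.000133, and adjusted p = 0.103 with an estimated correlation). Of 17 genes for collagen hydroxylation and crosslinking 8 were higher and none was lower over all genes, and 9 were higher and 3 lower adjusted over the list alone. PLOD2, a collagen lysyl hydroxylase, rose from 124.0 ± 13.2 to 550.1 ± 9.28 TPM (2.14 ± 0.10) and P4HA1 by 1.63 ± 0.07 (list camera adjusted p = 0.000323, and adjusted p = 0.103 with an estimated correlation). Of 12 genes of the glomerular basement membrane 6 were higher, including LAMB2 (0.75 ± 0.11) and LAMA5 (0.68 ± 0.11), with a median of 0.47 (adjusted p = 8.69e-06, and adjusted p = 0.137 with an estimated correlation). The extracellular matrix list shares COL4A1, COL4A2 and LAMC1 with the basement membrane list. Of its 23 tested genes 6 were higher, such as COL5A1 (0.69 ± 0.12), and 3 were lower, such as TNC (−0.85 ± 0.08). The matrix list did not pass (camera adjusted p = 0.0638), though it did with no filter (adjusted p = 0.0405) and at a mean of at least 5 TPM (adjusted p = 0.0472). Its median was 0.15, against 0.16 without control replicate 1 and 0.19 without DMOG replicate 2. Among 19 angiogenic and vasoactive factors 9 were higher and 3 lower, with FGF2 at −0.65 ± 0.10 (list adjusted p = 0.000323, and adjusted p = 0.103 with an estimated correlation).

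Of 37 listed podocyte markers 26 were tested, the others having a mean under 1 TPM, so the result covers only the expressed markers. Of those 26, 7 were higher and 1 was lower. Synaptopodin (SYNPO), an actin-binding protein of podocyte foot processes, rose from 14.5 ± 0.539 to 60.7 ± 6.27 TPM (1.99 ± 0.10, adjusted p = 0.000573), and INF2 rose by 0.74 ± 0.08. The intermediate filament gene NES was lower, at 7.31 ± 1.14 against 16.8 ± 1.45 TPM (−1.11 ± 0.14). The list median was 0.17 (camera adjusted p = 0.000710, and adjusted p = 0.103 with an estimated correlation). Parietal epithelium markers had a median of −0.46, with 5 of 11 lower and 2 higher, and did not pass as a list (camera adjusted p = 0.166).

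Proliferation and inflammatory genes were lower with DMOG. Of 31 cell cycle genes 24 were lower, for example AURKA (−1.11 ± 0.15) and CCNB2 (−1.08 ± 0.15), and only E2F1 was higher (0.37 ± 0.07), with a median of −0.54 (adjusted p = 7.15e-08, and adjusted p = 0.448 with an estimated correlation). Of 21 inflammatory mediators 15 were lower and none was higher, with a median of −1.0 (adjusted p = 7.82e-08, and adjusted p = 0.103 with an estimated correlation). The monocyte chemokine CCL2 stood at 4.92 ± 0.0129 against 71.2 ± 2.38 TPM (−3.61 ± 0.11, adjusted p = 0.000178). The adhesion molecule VCAM1 stood at 0.594 ± 0.136 against 14.8 ± 1.77 TPM (−3.30 ± 0.17, adjusted p = 0.000573). Of 24 interferon response genes 12 were lower and none was higher, with PSMB9 at −1.18 ± 0.13. That list had a median of −1.09 (adjusted p = 0.000109, and adjusted p = 0.50 with an estimated correlation). Of 41 ribosomal protein genes 9 were lower and none was higher, for example RPS27A (−0.56 ± 0.10), with a median of −0.22 (adjusted p = 4.22e-05, and adjusted p = 0.50 with an estimated correlation).

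Stress and lipid genes changed in part. Of 23 integrated stress response genes 8 were higher, with SLC7A5, an amino acid transporter gene, up by 1.76 ± 0.08, and 3 were lower, with ATF5 at −0.94 ± 0.13 (list adjusted p = 0.000711, and adjusted p = 0.490 with an estimated correlation). The endoplasmic reticulum chaperone list held 21 tested genes, not all of them chaperone genes. Of these 4 were higher, with ERO1A (1.36 ± 0.08) and EDEM1 (0.84 ± 0.09), and SEC61B was lower (−0.54 ± 0.06). That list had an adjusted p of 0.00743 (0.490 with an estimated correlation), or 0.0650 without DMOG replicate 1. Of 23 cholesterol synthesis genes 7 were higher, with LSS (0.83 ± 0.07) and SREBF2 (0.73 ± 0.07), and HSD17B7 was lower at −0.51 ± 0.14 (list adjusted p = 0.00288, and adjusted p = 0.236 with an estimated correlation).

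Among the 10 largest rises taken by the rule were also DEPP1, an autophagy-related FOXO target (259.8 ± 24.4 against 20.8 ± 0.960 TPM, 3.58 ± 0.11), and tissue factor (F3, 479.0 ± 109 against 51.3 ± 0.727 TPM, 3.18 ± 0.21). The other 5 were short RNAs or pseudogenes with 1.17 to 6.5 estimated reads per library on average: RNA5SP268, MIR6779, a Y_RNA copy, SCARNA8 and COX7A2P1. The first 4 of these are listed at 0 in both control libraries. Of the 10 largest falls, 8 were of the same kind and listed at 0 with DMOG, with 0.833 to 8 estimated reads on average (MT-TD, MCF2L2P1, MIR29A, MIR4730, MIR4322, SNORD14E, MT-TQ and RNU6-638P). Such reads are too few to give a fold change. In the ranking with at least 10 estimated reads, chosen after the values were seen, the further rises were HK2, ANGPTL4, INHBB (2.97 ± 0.32), LNCSRLR (2.96 ± 0.37) and ARG2 (2.71 ± 0.09). The further falls included HIF1A, the vitamin D hydroxylase gene CYP24A1 (20.4 ± 1.40 against 116.4 ± 0.880 TPM, −2.46 ± 0.09), the chemokine gene CXCL1 (373.0 ± 38.6 against 1771 ± 102 TPM, −2.25 ± 0.15) and the immediate early gene EGR1 (−2.12 ± 0.21).

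In all, limma called 3764 of 16969 genes between DMOG and control, 1453 higher and 2311 lower. Of these, 287 were at least 2-fold higher and 375 at least 2-fold lower on the log2(TPM + 1) scale. The balance of directions depended on scaling, since 38.6% of called genes were higher here, against 52.1% with median-ratio scaling and 48.1% with quantile normalization. The count was 270 without control replicate 1, 168 without control replicate 2, 943 without DMOG replicate 1 and 200 without DMOG replicate 2. Of 108 named genes past the threshold, from 34 to 101 stayed past it in those and the other leave-one-out fits, and NDRG1, VEGFA, HK2, SYNPO, HIF1A, CCL2 and VCAM1 did in all 6. CA9 reached adjusted p = 0.05215 in 1 of them.

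The second comparison asks which transcripts change in low oxygen. After 16 h of hypoxia 6 genes were higher than in control and none was lower. NDRG1 rose to 101.6 ± 13.1 TPM (1.78 ± 0.10, adjusted p = 0.0259) and DEPP1 to 69.1 ± 7.28 TPM (1.68 ± 0.11, adjusted p = 0.0261). APOL1, a secreted lipoprotein gene with kidney disease variants in human populations (ENSG00000100342, chromosome 22, 36253010 to 36267530, plus strand), rose from 123.1 ± 0.375 to 323.7 ± 4.05 TPM (1.39 ± 0.10, adjusted p = 0.0288). POU5F1 rose from 7.79 ± 0.00266 to 24.6 ± 3.34 TPM (1.54 ± 0.12, adjusted p = 0.0333), but its locus overlaps TCF19 and PSORS1C3 and it has related pseudogenes, so its reads are uncertain. The lysosomal ribonuclease gene RNASET2 rose by 1.19 ± 0.09 and the mTORC1 inhibitor gene DDIT4 by 1.16 ± 0.09 (both with adjusted p = 0.0333). All 6 were also higher with DMOG.

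Of the 32 HIF targets, NDRG1 and DDIT4 passed over all genes, and 22 were higher when adjusted over the list alone. The fold change was above 0 for 31 of 32, and in 30 both hypoxia libraries lay above both control libraries, an arrangement that chance gives for 16.7% of genes. The median was 0.54 (camera adjusted p = 8.00e-25, and adjusted p = 0.0999 with an estimated correlation). CA9 stood at 4.16 ± 2.16 TPM (1.39 ± 0.31, adjusted p = 0.180) and VEGFA at 147.2 ± 36.2 TPM (1.10 ± 0.16, adjusted p = 0.119), neither past the threshold. HIF1A stood at 147.1 ± 11.6 TPM (−1.13 ± 0.13, adjusted p = 0.0902), among the 5 lower genes with the smallest unadjusted p. The others were the transferrin receptor gene TFRC (−0.72 ± 0.08, adjusted p = 0.0792), C1QBP (−0.61 ± 0.08, adjusted p = 0.0908), AK6 (−0.79 ± 0.10, adjusted p = 0.108), whose locus overlaps TAF9, and SNORD14E, which is listed at 0 in hypoxia and has under 1 estimated read on average.

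No member of the other lists passed over all genes in hypoxia, apart from those 2 HIF targets, and the list tests rest on small shifts. Glycolysis had a median of 0.32, with 13 of 21 genes higher adjusted over the list alone and 1 lower (adjusted p = 8.99e-13, and adjusted p = 0.0999 with an estimated correlation). Lists above other genes were also collagen hydroxylation and crosslinking (median 0.23, adjusted p = 9.51e-07, and 0.0999 with an estimated correlation), angiogenic factors (0.16, adjusted p = 0.000155, and 0.140), glomerular basement membrane (0.31, adjusted p = 0.000449, and 0.317), extracellular matrix (0.10, adjusted p = 0.00330, and 0.339) and mitochondrially encoded genes (0.51, adjusted p = 8.90e-07, and 0.339). The last of these had a median of 0.21 without hypoxia replicate 2 and still passed (adjusted p = 0.000437), and extracellular matrix did not pass without control replicate 2 (adjusted p = 0.0834). Lists below other genes were ribosomal proteins (median −0.24, adjusted p = 8.36e-13, and 0.339 with an estimated correlation), cell cycle (−0.40, adjusted p = 5.58e-09, and 0.339), nuclear respiratory chain (−0.22, adjusted p = 8.65e-08, and 0.339) and TCA cycle (−0.15, adjusted p = 0.00333, and 0.339). The TCA cycle did not pass without hypoxia replicate 2 (adjusted p = 0.0716). Podocyte markers had a median of 0.00 (adjusted p = 0.227), with ACTN4 at −0.11 ± 0.08.

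Inflammatory mediators had a median of −0.02 in hypoxia (adjusted p = 0.687) and interferon response genes −0.23 (adjusted p = 0.125). The interferon list was below other genes without control replicate 1 (adjusted p = 0.00285) or without hypoxia replicate 1 (adjusted p = 0.00105). Demethylases (0.06, adjusted p = 0.227), oxygen sensing (0.00, adjusted p = 0.687), cholesterol synthesis (−0.12, adjusted p = 0.0757), endoplasmic reticulum chaperones (−0.10, adjusted p = 0.0757) and the integrated stress response (−0.03 with a camera direction above other genes, adjusted p = 0.790) did not pass. With no filter on low values cholesterol synthesis (adjusted p = 0.0166) and the chaperones (adjusted p = 0.0347) were below other genes.

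The count of 6 genes was small beside 2743 with an unadjusted p under 0.05, 1078 of them higher and 1665 lower. It was 45 with at least 10 estimated reads (41 higher and 4 lower) and 329 with voom on estimated reads (185 higher and 144 lower), and all 6 genes were among those called by both. It fell to 1 without control replicate 1 and to 0 with any other library left out, and none of the 6 genes passed in those fits.

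**Figure D2:**
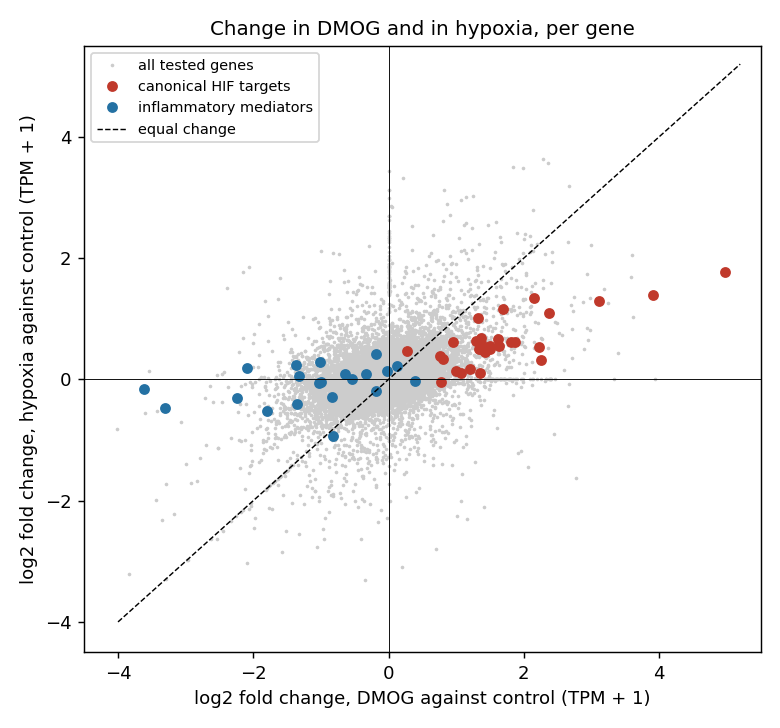
Log2 fold change against control (TPM + 1) with DMOG on the horizontal axis and in hypoxia on the vertical axis, a point per tested gene, with 32 HIF targets in red, 21 inflammatory mediators in blue and a dashed line at equal change. HIF targets lie right of 0 and, in 31 of 32, below the line of equal change, and 19 of 21 inflammatory mediators lie left of 0, with hypoxia values from −0.93 to 0.42. Both axes share the control libraries.

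The third comparison tests the difference between the stimuli. HIF targets were higher with DMOG than in hypoxia: 27 of 32 passed, none was lower, and the median difference was 0.94 (camera adjusted p = 8.13e-24, and adjusted p = 0.130 with an estimated correlation). NDRG1 differed by 3.20 ± 0.10 (adjusted p = 0.000452), CA9 by 2.53 ± 0.31, SLC2A3 by 1.93 ± 0.13 and ANGPTL4 by 1.81 ± 0.14. Among the 30 targets that rose with DMOG, the hypoxia log2 fold change was a median 36.0% of the DMOG value, with a range of 7.48% to 76.1%. DDIT4 differed by 0.53 ± 0.09, and PDK1 (0.48 ± 0.17, adjusted p = 0.111), PFKFB4 (0.32 ± 0.24) and MIR210HG (0.32 ± 0.34) did not pass. APOL1 stood at 288.2 ± 37.3 TPM with DMOG and 323.7 ± 4.05 TPM in hypoxia, a difference of −0.17 ± 0.10 that did not pass (adjusted p = 0.278).

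HIF1A was lower with DMOG than in hypoxia (−1.40 ± 0.13, adjusted p = 0.00543) and EPAS1 higher (0.83 ± 0.11, adjusted p = 0.0129). The oxygen sensing list passed (median 0.22, adjusted p = 0.0243, and 0.533 with an estimated correlation) but not without DMOG replicate 1 (adjusted p = 0.1005), without hypoxia replicate 1 (adjusted p = 0.0739) or at a mean of at least 5 TPM (adjusted p = 0.155). CCL2 (−3.46 ± 0.11), VCAM1 (−2.83 ± 0.17) and GBP1 (−1.89 ± 0.23) were lower with DMOG, as were 14 of 21 inflammatory mediators (median −0.95, adjusted p = 1.81e-09, and 0.130 with an estimated correlation) and 7 of 24 interferon response genes (median −0.81, adjusted p = 8.93e-05, and 0.555). NES stood at 7.31 ± 1.14 TPM with DMOG and 26.5 ± 0.983 TPM in hypoxia (−1.74 ± 0.14, adjusted p = 0.00379), while SYNPO was higher with DMOG (0.95 ± 0.10, adjusted p = 0.00741). Podocyte markers had a median difference of 0.21 (adjusted p = 0.000577, and 0.130 with an estimated correlation). Parietal epithelium markers moved the other way (5 of 11 lower and 2 higher, median −0.48, adjusted p = 0.00840, and 0.192), and all 6 tested tubule markers had differences below 0, though that list did not pass (adjusted p = 0.307).

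Glycolysis genes were higher with DMOG in 12 of 21 and lower in none, with HK2 at 2.16 ± 0.10 (list adjusted p = 1.06e-09, and 0.130 with an estimated correlation). Cholesterol synthesis genes were higher in 8 of 23, with LSS at 0.77 ± 0.07, and lower in 1, EBP (list adjusted p = 1.14e-05, and 0.130 with an estimated correlation). Lists above other genes were also demethylases (7 of 22 higher, adjusted p = 0.000161, and 0.130 with an estimated correlation), the integrated stress response (8 of 23 higher, including TRIB3 at 1.25 ± 0.09, and 3 lower, adjusted p = 8.93e-05, and 0.370), endoplasmic reticulum chaperones (4 of 21 higher and 1 lower, adjusted p = 5.58e-05, and 0.314), glomerular basement membrane (3 of 12 higher, adjusted p = 0.0126, and 0.314) and collagen hydroxylation and crosslinking (7 of 17 higher and 3 lower, adjusted p = 0.0170, and 0.192). Angiogenic factors passed (5 of 19 higher and 1 lower, adjusted p = 0.0212, and 0.192), but not without DMOG replicate 1 (adjusted p = 0.0515) or hypoxia replicate 2 (adjusted p = 0.0579). The lower genes of collagen crosslinking included LOXL1 (−0.65 ± 0.11) and LOXL4 (−0.40 ± 0.08).

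Below other genes were the nuclear respiratory chain (2 of 43 lower, median −0.19, adjusted p = 0.00140, and 0.506 with an estimated correlation) and cell cycle genes (1 of 31 lower, MCM5, and 1 higher, E2F1, median −0.27, adjusted p = 0.00407, and 0.572). Without hypoxia replicate 1 neither passed, with adjusted p = 0.0523 and 0.443. Mitochondrially encoded genes (median −0.16, adjusted p = 0.313), ribosomal proteins (0.00, adjusted p = 0.447), the TCA cycle (−0.05, adjusted p = 0.829) and extracellular matrix (−0.03 with a camera direction above other genes, adjusted p = 0.947) did not pass, and without hypoxia replicate 1 the first 2 did (adjusted p = 0.000122 and 0.000625).

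The largest differences by the rule were again mostly short RNAs listed at 0 in a group. RNA5SP268, RNU6-216P, MIR339, SNORD88A, SCARNA8, RPL39P36 and SNORD51 had 1.17 to 2.5 estimated reads per library on average and were listed at 0 in hypoxia. MIR6739, MIR23C, MIR208B, SNORD11, a Y_RNA copy and MCF2L2P1 were listed at 0 with DMOG, and SNORD69 had 5.5 estimated reads. With at least 10 estimated reads the further differences included ARG2 (2.36 ± 0.09), LINC01293 (2.21 ± 0.28) and CYP24A1 (−2.55 ± 0.09), the last of which stood at 124.7 ± 10.2 TPM in hypoxia. In all, 2102 genes differed, 965 higher and 1137 lower with DMOG. The count was 352 and 341 without control replicate 1 or 2, 20 and 0 without DMOG replicate 1 or 2, and 29 and 236 without hypoxia replicate 1 or 2. CCL2, NDRG1 and HK2 passed in 5 of these 6 fits.

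**Figure D3:**
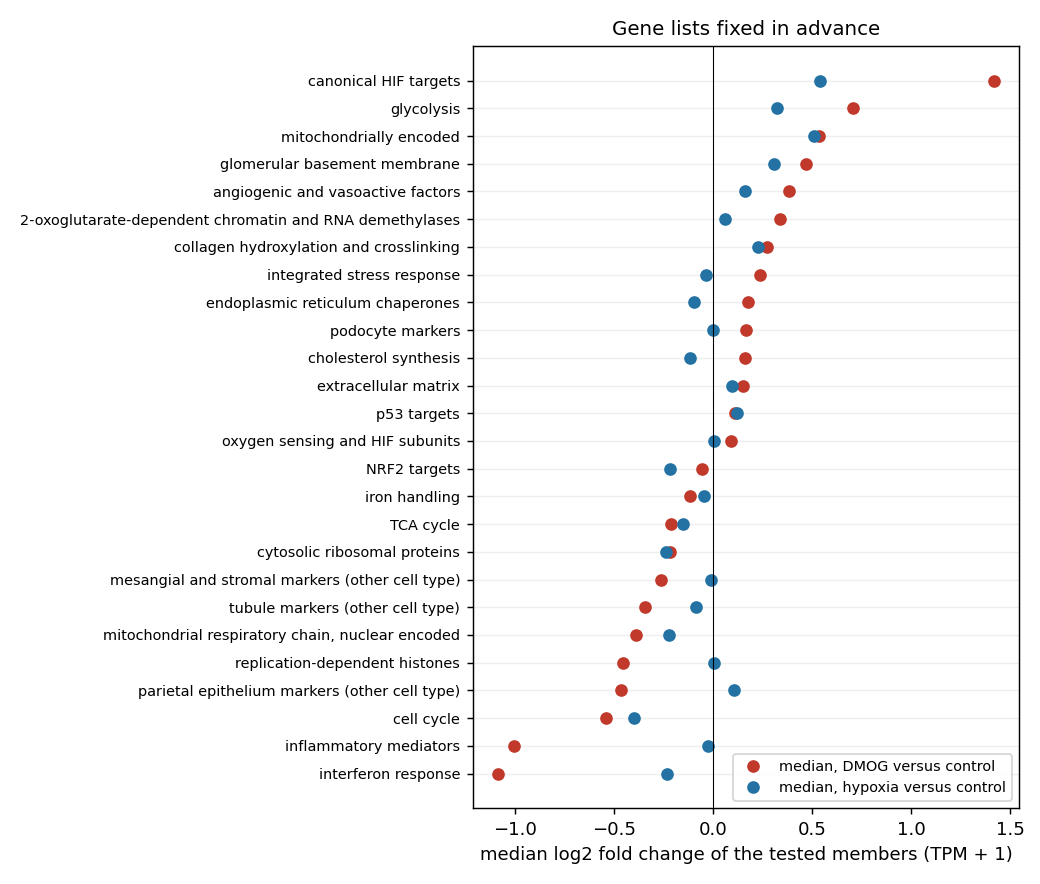
Median log2 fold change (TPM + 1) of the tested members of 26 gene lists, with DMOG against control in red and hypoxia against control in blue. HIF targets have medians of 1.42 and 0.54, and interferon response genes −1.09 and −0.23.

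All 6 genes higher in hypoxia were among the 1453 higher with DMOG, no gene was lower in both and none passed in opposite directions. Under other settings genes were also lower in both, 3 at a mean of at least 5 TPM, 3 with at least 10 estimated reads and 127 of 264 shared genes with voom. Independent lists of these sizes would share 0.514 higher genes. Simulated unchanged groups against the same controls shared 0.02 higher and 0.05 lower genes on average. Those groups were unchanged by design and had few calls to share, so they cannot show whether shared controls explain the overlap. Fold changes of the comparisons correlated across genes with r = 0.447, against 0.502 in simulated unchanged groups, so the correlation does not separate a shared response from shared controls. Nor did the rank correlation (0.449 against 0.450 simulated) or the share of genes with the same direction (67.3% against 66.7%). Their covariance was 0.119 against 0.0567 simulated, a difference of 0.0622. With 2 control libraries the controls could not be split into parts of 2.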

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

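No named gene or gene list changed direction while past the threshold under any alternative. Over all alternatives, 5231 values of named genes kept their side of the threshold, 1052 fell short of it and 47 newly passed it. For gene lists these numbers were 1212, 77 and 31. With no filter on low values, limma called 2264 genes for DMOG versus control, 943 for DMOG versus hypoxia and 0 for hypoxia versus control, with an overlap of 0. With no trend in the prior variance the counts were 1953 and 502, and hypoxia had 8 genes, of which 0 were among the 6, and the overlap was 0. Fits of only the 2 groups compared gave 0 genes for hypoxia, 352 for DMOG versus hypoxia and an overlap of 0. That fit has fewer residual degrees of freedom. Requiring an absolute log2 fold change of at least 1 left 662 genes for DMOG versus control and 411 for DMOG versus hypoxia, by construction. For hypoxia, where 6 genes were called, the count was 3 with a pseudocount of 5, 10 with median-ratio scaling, 13 with quantile normalization and 34 at a mean of at least 5 TPM. The overlap, also 6, was 3 with the pseudocount of 5, 12 with quantile normalization and 31 at 5 TPM. The cause was not tested. Of the alternatives chosen after seeing the data, at least 10 estimated reads gave 45 hypoxia genes and an overlap of 42. Voom on estimated reads gave 329 hypoxia genes, 3896 for DMOG versus hypoxia, 5254 for DMOG versus control and an overlap of 264. With an estimated correlation, 0 of 18 lists for DMOG versus control, 0 of 13 for hypoxia and 0 of 18 for DMOG versus hypoxia passed. The robust prior does not enter camera, so it gives no list count. With each library left out in turn, counts ranged from 168 to 3142 for DMOG versus control, from 0 to 1 for hypoxia, from 0 to 352 for DMOG versus hypoxia and from 0 to 1 for the overlap. Lists ranged from 15 to 21, from 13 to 14 and from 15 to 18. In those fits the lone library of a group is assumed to vary like the other groups. Of the 3764 genes called between DMOG and control, 108 had under 10 estimated reads per library. No paired analysis was possible because the labels give the groups no shared replicate numbers.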

Other observations

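Some gene lists fit none of the comparisons' main themes. NRF2 targets, the antioxidant genes, were below other genes in hypoxia (median −0.22, camera adjusted p = 0.000517, and adjusted p = 0.145 with an estimated correlation), with no member past the threshold. Under DMOG 2 of 17 were higher, HMOX1 (1.20 ± 0.18) and TXNRD1 (0.61 ± 0.09), and 4 were lower, with AKR1B1 at −0.78 ± 0.10 and NQO1 at −0.32 ± 0.07. Their median was −0.06 with a camera direction above other genes (adjusted p = 0.831). Between the stimuli the NRF2 list was higher with DMOG (median 0.24, adjusted p = 0.0160, and 0.192 with an estimated correlation). Of 18 p53 targets 5 were higher with DMOG, including GDF15 (0.71 ± 0.09) and ZMAT3 (0.61 ± 0.10), and BAX was lower (−0.30 ± 0.07), with a list adjusted p of 0.00676 (0.490 with an estimated correlation). In hypoxia the p53 list had a median of 0.12 (adjusted p = 0.00273, and 0.339 with an estimated correlation) and did not pass without control replicate 1 (adjusted p = 0.0516) or hypoxia replicate 2 (adjusted p = 0.0716). Between the stimuli it had an adjusted p of 0.385. Of 12 iron handling genes 2 were higher and 3 lower with DMOG. They did not pass as a list with DMOG (median −0.12 with a camera direction above other genes, adjusted p = 0.831), in hypoxia (−0.04, adjusted p = 0.137) or between them (−0.09, again with a direction above other genes, adjusted p = 0.301). Without hypoxia replicate 2 they were below other genes in hypoxia (adjusted p = 0.0452). TFRC was 0.87 ± 0.08 higher with DMOG than in hypoxia (adjusted p = 0.00543). Replication-dependent histones had a median of −0.45 with DMOG (adjusted p = 0.0556), 0.00 in hypoxia (adjusted p = 0.673) and −0.50 between the stimuli (adjusted p = 0.0357, and 0.561 with an estimated correlation). The last of these did not pass under 5 alternatives (adjusted p = 0.0507 to 0.1555). The histones were below other genes with DMOG under 5 alternatives (adjusted p = 0.00198 to 0.0444), and above them in hypoxia without control replicate 2 (adjusted p = 0.0153).

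Parietal epithelium markers had a median of −0.46 with DMOG (adjusted p = 0.166), 0.11 in hypoxia (adjusted p = 0.0757) and −0.48 between the stimuli (adjusted p = 0.00840, and 0.192 with an estimated correlation). In hypoxia they were above other genes under 5 alternatives (adjusted p = 0.0267 to 0.0453). Of 11 tested parietal markers 5 were lower with DMOG than in control, such as CLDN1 (−0.59 ± 0.10), and 2 were higher, AKAP12 (1.08 ± 0.13) and PAX8 (0.62 ± 0.08). VCAM1 is both in this list and among the inflammatory mediators. The 6 tested tubule markers, all with fold changes below 0 with DMOG against control and against hypoxia, had medians of −0.34, −0.08 and −0.28 in DMOG, hypoxia and their difference (adjusted p = 0.305, 0.958 and 0.307), with the hypoxia value opposite to its camera direction, and without DMOG replicate 2 they were below other genes against control (adjusted p = 0.0462) and against hypoxia (adjusted p = 0.04005). Mesangial and stromal markers had medians of −0.26, −0.01 and −0.27 (adjusted p = 0.831, 0.177 and 0.411), the second opposite to its camera direction and past the threshold at a mean of at least 5 TPM (adjusted p = 0.0351), with 2 of 12 higher with DMOG, such as NOTCH3 (0.76 ± 0.14), and MCAM lower (−0.31 ± 0.06). Among the 2 tested endothelial markers EHD3 was higher with DMOG (0.43 ± 0.11) and ESAM stood at 1.15 ± 0.0473 TPM in control. The 3 tested leukocyte markers had medians of −0.21, 0.35 and −0.56, with CD14 at 3.92 ± 0.0293 TPM in control, and none passed.

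Patterns were weighed below as hypotheses on the data that raised them. The tests on HIF1A and on inflammatory genes were chosen only after their results were seen. The tests on the covariance of the stimuli were written down first.

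The fold changes of DMOG and hypoxia covaried beyond what simulated unchanged groups gave. Shared control libraries alone would remove this covariance once each stimulus has its own control library. With separate control libraries it was 0.0491 in one assignment and 0.0493 in the other, above the highest of 100 simulated values, 0.00752. For rescaling by mitochondrial transcripts, the covariance without mitochondrially encoded genes was 0.121, above the highest simulated value of 0.0605. This test cannot decide, since rescaling shifts nearly all genes alike and a covariance over genes hardly responds to such a shift. A candidate explanation is a partly shared response, weaker in hypoxia, but handling common to the treated cultures is not recorded in the labels and stays open.

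HIF1A was lower with DMOG while the overlapping HIF1A-AS3 was higher. Scaling is argued against as the whole cause, since the HIF1A log2 fold change was −2.45 to −2.49 under the other scalings. Reads of HIF1A counted for HIF1A-AS3 are argued against as the cause of the fall, since the gain of HIF1A-AS3, as a share of each library's estimated reads, was 4.63% of the loss of HIF1A and at most 5.47% over pairs of libraries. A fixed share of those reads is argued against as the cause of the rise, since HIF1A-AS3 would then fall with HIF1A but changed by 3.25 ± 0.19, while a share that differs with DMOG stays open. HIF1A was also below both control libraries in both hypoxia libraries (−1.13 ± 0.13, not past the threshold), consistent with a fall of its transcript under both stimuli, possibly a feedback, and whether the antisense RNA takes part was not tested.

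Inflammatory and interferon genes were lower with DMOG, and neither list passed in hypoxia, though the interferon list did without control replicate 1 (adjusted p = 0.00285) or hypoxia replicate 1 (adjusted p = 0.00105). Of 45 tested genes in these lists, 27 were lower with DMOG, with a summed difference of 4667 TPM, and the median over all 45 was −1.01. Scaling that moves all genes alike is argued against, since this median minus that of all tested genes was −0.94, a gap that such a shift cannot make. The gap was −0.93 at the nearest to 0 under the other scalings. That adds little, because median-ratio scaling and removal of mitochondrially encoded genes leave such a gap nearly unchanged by construction. Fewer leukocytes in the DMOG cultures is argued against, because the highest leukocyte marker reached 3.94 TPM in a control library. This was largely settled by the design, since the cultures were of a podocyte cell line. A single DMOG or hypoxia library is argued against for the difference between the stimuli. The median of that difference over both lists stayed between −0.94 and −0.67 with each library left out. Control libraries do not enter this median, so it cannot decide on a single control library. An action of DMOG beyond that of hypoxia may thus be followed up, while dose and the unrecorded oxygen level stay open.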
